A study of Sus scrofa with 67 samples.

How the data were processed

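Longissimus dorsi muscle of 67 Swiss Large White pigs was measured by RNA sequencing. According to the design text the animals came from 20 litters, 33 were females and 34 castrated males, and the tissue was snap frozen. Per the labels' protocols RNA was extracted with the RNeasy Plus Universal kit and libraries followed a standard Illumina protocol. The authors deposited a table of read counts per gene symbol, 18158 genes by 67 libraries, as raw whole numbers. Per the submitters' processing notes the genome build was Sscrofa11.1 and DESeq2 was used, with no version. The aligner, the counting program, its strand setting and filters are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes, and of near-identical copies such as ribosomal protein genes and their pseudogenes, cannot be assigned with certainty.

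Total deposited counts were 26680567 to 36935497 per library. Low even counts were more frequent than odd ones, with 18638 values of 2 against 3454 values of 1 and 14829 values of 4 against 10646 values of 3. The files do not say why, and the spread between libraries, which the tests use, includes this. The highest correlation of any pair of libraries across genes was 0.984 (Pearson, log2 of CPM plus 0.5), and no pair was counted as 1 sample. Of the gene names 93.6% (16989) were found in the RefSeq gene table for Sscrofa11.1, from which coordinates are given, and 2525 names are LOC numbers.

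Groups were taken from the library titles: BL (n = 7), LP (n = 6), STD (n = 6), STD-STD, LP-STD, LP-STD10 and LP-STD20 (n = 12 each). The meaning of BL is not stated in the labels. Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, robust dispersions, quasi-likelihood F test), with Benjamini-Hochberg adjustment and a threshold of 0.05. LP against STD used their 12 libraries (12584 genes). Comparisons within the second period used its 48 libraries (13032 genes), and those across periods or with BL used all 67 (13517 genes). Log2 differences are from this fit with their SE, and CPM values are means with the SD over libraries.

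Gene lists for 40 pathways and cell types were fixed before the data were examined, as were the tests, groups and most alternatives. Lists with at least 5 measured members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, the p-values being adjusted over the lists of a comparison, and again with an estimated correlation. The list tests for the interaction and for LP-STD10 and LP-STD20 against STD-STD were added after seeing the data. Of all lists and comparisons only fatty acid use and the amino acid response in STD against BL, and ribosomal proteins in the interaction, passed with an estimated correlation. List medians are medians of the edgeR log2 differences unless limma voom is named. List scores, the mean log2 CPM of the members per library (prior count 2), were compared by two-sided permutation tests, exact with fewer than 10 libraries in a group and with 100000 permutations otherwise.

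Named genes followed a fixed rule. Among genes past the threshold with a symbol other than a LOC number and an average log2 CPM of at least 1, the 10 largest rises and 10 largest falls could be named, with up to 4 passing members of each list. All were eligible if fewer than 20 passed, and the 3 lowest p-values per direction if none did. A set of focus genes fixed beforehand could be named in any comparison. Others are said to be chosen after their values were seen.

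Alternatives were RLE factors, DESeq2 1.42.0, limma voom with quality weights, no count filter, a filter at a CPM of 1, the replicate number as a block, the summed Y-linked counts as a covariate, 2 surrogate variables (sva 3.50.0), another set of libraries in the fit, blocks of 16 consecutive library numbers and a threshold of 0.10. Sums over runs of 4 libraries, correlated runs (limma voom without quality weights, one correlation for all genes) and fits without single libraries were added after seeing the data. Tests of list scores over means of runs and the fatty acid use score without PDK4 were also added then. So were differences of list scores without each library in turn. These are given where they moved by over 1.5 times, for lists reported in that comparison. In comparisons across periods the libraries outside the runs were blocks of their own. Figures and permutations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

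The tests were checked on simulated counts with 200 changed genes, drawn from the real means and library sizes. Libraries were drawn as independent, with no differences between runs of 4 libraries. The shares and false calls below therefore do not cover such differences, which the real second-period libraries had. For LP against STD 40.3% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 97% of those changed 4-fold were recovered, with 5 unchanged genes called. For LP-STD10 against LP-STD the shares were 83.6%, 95.5% and 100%, with 8 unchanged genes called. For STD against BL they were 64.2%, 88.1% and 100%, with 14 unchanged genes called.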

Results

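RNA was sequenced from the longissimus dorsi, a back muscle made up mostly of fast fibres, of 67 Swiss Large White pigs, and the deposited table holds read counts for 18158 genes. For the first 4 weeks after weaning the pigs ate either a standard diet or a low protein diet with 81% of its total and 79% of its digestible crude protein. Libraries named for these diets form the groups STD (n = 6) and LP (n = 6). In weeks 5 to 8 pigs from the standard diet stayed on it (STD-STD, n = 12). Pigs from the low protein diet moved to the standard diet (LP-STD, n = 12) or to that diet with 10% (LP-STD10, n = 12) or 20% (LP-STD20, n = 12) more digestible lysine. A further 7 libraries carry the label BL, which the labels do not explain, and were kept as a group of their own. The design text mentions 7 piglets that took no further part, without saying whether BL stands for them, so the age and diet behind BL are not known.

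Total counts ranged from 26680567 to 36935497 per library, from 26680567 to 34338980 in BL and from 31974264 to 35769605 in STD. The replicates are separate pigs according to the design text, and sex, litter and the week of sampling are not given for each library. Second-period libraries were numbered in runs of 4 consecutive libraries of one group, 3 runs per group. A single test compared the runs within all 4 second-period groups together, so it does not say in which group a gene differed. In it 740 of 13032 genes differed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), below said to differ between runs of one group. Among them were 11 of 19 circadian genes, such as DBP and NR1D1, and 9 of 18 heat shock genes, such as DNAJB1. After libraries were shuffled among the runs of their group the highest count of differing genes was 2. The second-period comparisons are therefore also given with counts summed over runs. Tests of second-period list scores treat libraries as independent, and over the 6 means of runs the smallest p an exact test can give is 0.10.

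The comparison of LP with STD addresses the low protein diet of the first period. Genes of ribosomal proteins, which with ribosomal RNA form the translating ribosome, lay lower in LP as a set, with a median log2 difference of -0.26 and 46 of 47 measured members below 0. RPL15 (-0.34 ± 0.06), RPS15 (-0.42 ± 0.08) and RPLP0 (-0.36 ± 0.07) are examples chosen after their values were seen (log2 ± SE, n = 6 per group). Genes of the extracellular matrix, the collagen network around fibres, lay higher with a median of 0.30, COL3A1 (a fibrillar collagen) by 0.44 ± 0.12. Cell division genes lay higher with a median of 0.35, and amino acid response genes, which cells induce through ATF4 when amino acids run short, lay lower with a median of -0.30. STD replicate 4 stood apart in the cell division score, at 1.82 against 2.46 to 2.78 in the other STD libraries and 2.46 to 3.03 in LP. Without it, chosen after seeing the data, the median of that list (limma voom) moved from 0.36 to 0.22 (camera adjusted p = 1.09e-06), and the score difference from 0.37 to 0.25. LP replicates 1 and 2, numbered 8 and 9 among the libraries, stood apart in PDK4, at 343 and 326 CPM against 3.07 to 132 in the other LP libraries, and in the fatty acid use score, at 6.05 and 6.05 against 5.30 to 5.81. Without both, chosen after seeing the data, the median of the amino acid response list (limma voom) moved from -0.44 to -0.16 (camera adjusted p = 0.0166), and without LP replicate 2 alone to -0.16 (camera adjusted p = 0.0050). Without LP replicate 2 the score difference of this list moved from -0.62 to -0.39. The score of this list was 3.92 and 4.13 in LP replicates 2 and 5, 5.31 to 6.20 in the other LP libraries and 4.72 to 6.29 in STD (exact permutation test over all 12, adjusted p = 0.721). In LP fast fibre (-0.17) and nerve (-0.28) genes lay lower (median log2 difference, camera adjusted p 0.00124 to 0.0464, and 0.796 to 0.895 with an estimated correlation). The score difference of fast fibre genes moved from -0.10 to -0.05 without STD replicate 3, -0.18 without STD replicate 4, -0.07 without LP replicate 3 and -0.06 without LP replicate 6. Proteasome, cholesterol synthesis and glycolysis genes also lay lower by camera with the preset correlation, but not with an estimated one. The proteasome score difference moved from -0.07 to -0.05 without STD replicate 2 or 3. That of cholesterol synthesis moved from -0.20 to -0.06 without STD replicate 1, and that of glycolysis from -0.19 to -0.12 without STD replicate 3. Without STD replicate 4 slow fibre (0.36 against 0.09 with it, camera adjusted p = 0.0036), lymphocyte (0.57 against 0.36 with it, camera adjusted p = 0.0036), macrophage (0.19 against 0.14 with it, camera adjusted p = 0.0252) and fibroadipogenic genes (0.20 against 0.13 with it, camera adjusted p = 0.0036) lay higher (limma voom medians, preset correlation).

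The ribosomal list gave camera adjusted p = 3.7e-35, and adjusted p = 0.249 with an estimated correlation. For the extracellular matrix list camera gave adjusted p = 1.23e-16, and adjusted p = 0.249 with an estimated correlation. For cell division it gave adjusted p = 7.21e-11, and adjusted p = 0.796 with an estimated correlation. For the amino acid response it gave adjusted p = 1.03e-05, and adjusted p = 0.895 with an estimated correlation. The mean log2 CPM of the ribosomal list was 7.53 ± 0.07 (SD) in LP and 7.78 ± 0.11 in STD, and the highest LP library (7.62) lay below the lowest STD library (7.63). The exact two-sided permutation test gave p = 0.00216 (n = 6 per group), the smallest it can give, and 0.0844 after adjustment over 39 lists. It treats libraries as independent, while the STD libraries were numbered in an unbroken block, 10 to 15. Adjusted over the list alone, 36 ribosomal genes were lower and 13 of 32 matrix genes were higher.

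Over all 12584 genes 0 passed the edgeR test, 1139 had an unadjusted p under 0.05, limma voom with quality weights called 0 and DESeq2 called 129 (36 higher, 93 lower). The lowest p-values that did not pass belonged to NMRK2, a kinase of the NAD pathway that is enriched in muscle (-1.75 ± 0.24, adjusted p = 0.0783), and PIK3R1, the regulatory subunit of phosphoinositide 3-kinase (-0.98 ± 0.15, adjusted p = 0.0783). NMRK2 averaged 30.0 ± 6.86 CPM (SD) in LP and 101 ± 36.8 CPM in STD. In Sscrofa11.1 it lies on chromosome 2, 74786642 to 74791317. On the side of higher values ADAM12, a metalloprotease, had the lowest p (0.70 ± 0.12, adjusted p = 0.117), followed by SELENON (0.31 ± 0.06, adjusted p = 0.18) and CERCAM (0.45 ± 0.09, adjusted p = 0.18).

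**Figure D1:**
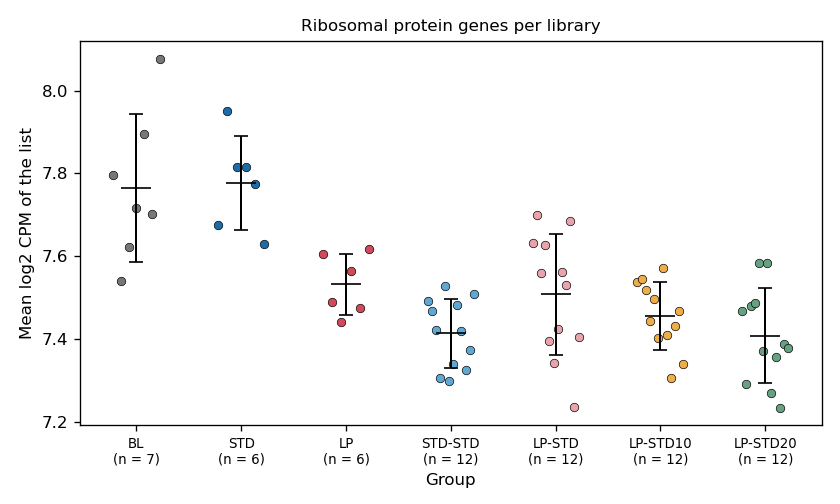
Mean log2 CPM of the ribosomal protein genes in each library (points) by group, with the group mean and SD as bars. The 6 LP libraries lie below the 6 STD libraries, and the means of the 4 second-period groups lie below the STD mean.

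The STD-STD and STD libraries are both named for the standard diet, in the second and the first period. Ribosomal protein genes fell, 41 of 47 of them past the threshold, for example RPL27A (-0.47 ± 0.06, adjusted p = 3.84e-07), RPL10A (-0.67 ± 0.09) and RPS2 (-0.56 ± 0.08). Amino acid response genes fell, 18 of 35, with the glutathione-degrading enzyme CHAC1 (-3.61 ± 0.81), the ATF4 target TRIB3 (-2.94 ± 0.69) and the stress-induced sestrin SESN2 (-2.97 ± 0.66). Immediate early genes, which respond to stimulation within minutes, rose (15 of 26, with 1 lower), among them FOS (6.56 ± 0.96, adjusted p = 2.25e-06), FOSB (4.46 ± 0.98) and EGR1 (4.35 ± 0.73). Respiratory chain genes fell in 27 of 62 cases, such as SDHB (-0.42 ± 0.09), and cell division genes in 9 of 29, such as MKI67 (-0.87 ± 0.25).

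FOS averaged 367 ± 388 CPM (SD, n = 12) in STD-STD and 3.91 ± 2.78 CPM (n = 6) in STD. Its means in the 3 runs of STD-STD were 533, 491 and 77.8 CPM (n = 4 each). In the test of runs over the 4 second-period groups together, 7 of 26 immediate early genes differed, EGR1 among them but not FOS. In all, 2150 of 13517 genes passed (edgeR), 1083 higher and 1067 lower. The translation repressor EIF4EBP1 (-1.28 ± 0.20, adjusted p = 4.33e-06) and the receptor IGF1R (-0.95 ± 0.22) fell, and the S6 kinase gene RPS6KB1 rose (0.42 ± 0.08). The secretory granule gene CHGB rose by 4.58 ± 0.59. LDHA, which makes lactate, rose (0.72 ± 0.16), and glutathione reductase (GSR) fell (-0.90 ± 0.14).

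Adjusted over the list alone, 43 ribosomal, 21 amino acid response, 29 respiratory chain and 15 cell division genes were lower, and 15 immediate early genes were higher. As sets the ribosomal list gave camera adjusted p = 1.4e-37, and adjusted p = 0.142 with an estimated correlation. The amino acid response gave adjusted p = 1.38e-08, and adjusted p = 0.806 with an estimated correlation. The immediate early genes gave adjusted p = 1.05e-06, and adjusted p = 0.806 with an estimated correlation. The respiratory chain gave adjusted p = 7.48e-10, and adjusted p = 0.806 with an estimated correlation. Cell division gave adjusted p = 1.24e-06, and adjusted p = 0.806 with an estimated correlation. In STD-STD macrophage (0.56) genes lay higher, and slow fibre (-0.38) and endothelial (-0.21) genes lay lower (median log2 difference, camera adjusted p 0.0164 to 0.0344, and 0.806 with an estimated correlation). Without STD replicate 4, chosen after seeing the data, the slow fibre (limma voom median -0.09 against -0.31 with it, camera adjusted p = 0.361) and endothelial lists (-0.21 against -0.22 with it, camera adjusted p = 0.0813) no longer passed camera. The score difference of slow fibre genes moved from -0.47 to -0.24 without STD replicate 4. With correlated runs of 4 libraries (limma voom) 1463 genes passed, 1449 of them shared, and FOSB (adjusted p = 0.0669) and TRIB3 (adjusted p = 0.0626) were no longer called. The design does not separate the period from age, whose value at sampling is not given, or from the runs in which its libraries were numbered.

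The interaction asks whether the change from the first to the second period differed between pigs that began on the low protein and on the standard diet. Of 47 ribosomal protein genes 13 had a positive interaction past the threshold, that is, a more positive change in pigs that began on the low protein diet. Among them were RPS4X (0.50 ± 0.09, adjusted p = 0.0146), RPL15 (0.48 ± 0.09) and RPL10A (0.60 ± 0.14). The epidermal growth factor family ligand BTC (1.81 ± 0.40, adjusted p = 0.0317), NMRK2 (1.58 ± 0.37, adjusted p = 0.0446) and the translation initiation factor gene EIF2S2 (0.87 ± 0.19) were also positive. RPS4X averaged 338 ± 27.3 CPM (SD) in LP and 386 ± 36.5 in LP-STD, against 436 ± 25.5 in STD and 351 ± 23.6 in STD-STD. The score of the whole ribosomal list did not rise from LP (7.53 ± 0.07, SD) to LP-STD (7.51 ± 0.15). It was lower in STD-STD (7.41 ± 0.08) than in STD (7.78 ± 0.11). Amino acid response genes had a positive median interaction of 0.67, with 5 of 35 higher when adjusted over the list alone, and ASNS (asparagine synthetase) at 1.36 ± 0.60, adjusted p = 0.518.

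In all 22 of 13517 genes passed the edgeR test, 21 positive and 1 negative, CDHR5 (-6.46 ± 1.48, adjusted p = 0.0393), which was chosen after its value was seen. The ribosomal list gave camera adjusted p = 2.73e-50, and adjusted p = 0.0116 with an estimated correlation, and 36 members passed when adjusted over the list alone. The amino acid response gave camera adjusted p = 1.61e-14, and adjusted p = 0.163 with an estimated correlation. In the interaction fast fibre (0.28) genes lay higher, and slow fibre (-0.46), extracellular matrix (-0.44), macrophage (-0.66), lymphocyte (-0.66), fibroadipogenic (-0.23) and erythroid (-0.87) genes lay lower (median log2 difference, camera adjusted p 2.33e-11 to 0.0345, and 0.158 to 0.708 with an estimated correlation). The score difference of slow fibre genes moved from -0.24 to -0.14 without LP replicate 1, -0.47 without STD replicate 4 and -0.12 without LP replicate 6. The contrast uses the same LP and STD libraries as the restriction comparison, so both share the chance values of these 12 libraries. With correlated runs of 4 libraries (limma voom), chosen after seeing the data, 0 genes passed and 857 had an unadjusted p under 0.05, with RPS4X at 0.49 (adjusted p = 0.058), and the list tests were not repeated in that fit. Counts were 83 with DESeq2, 73 with limma voom and quality weights and 52 with only the compared groups in the fit.

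In STD compared with the libraries labelled BL, genes of fatty acid use fell in 19 of 28 cases. They included both subunits of the trifunctional protein of beta-oxidation, HADHA (-0.91 ± 0.10, adjusted p = 4.15e-10) and HADHB (-0.96 ± 0.10), the carnitine palmitoyltransferase CPT2 (-1.63 ± 0.18, adjusted p = 2.32e-09) and the mitochondrial carrier UCP3 (-2.88 ± 0.48, adjusted p = 7.1e-05). Genes of the amino acid response rose in 23 of 35 cases, such as the serine synthesis genes PSAT1 (3.88 ± 0.76, adjusted p = 0.000628) and PHGDH (3.19 ± 0.76) and ASNS (2.81 ± 0.49, adjusted p = 0.000144), and 1 fell (NUPR1, chosen after its value was seen). Cholesterol synthesis genes rose in 11 of 24 cases, for example LSS (1.21 ± 0.24) and DHCR7 (1.06 ± 0.22). The fatty acid synthesis enzymes FASN (2.09 ± 0.52) and SCD (2.57 ± 0.67) rose as well. BL libraries were numbered 1 to 7 and STD libraries 10 to 15, so the label cannot be told apart from the place in the numbering. The fatty acid use score was 6.31 to 6.67 in BL and 5.27 to 5.66 in STD. It was 6.05 and 6.05 in LP libraries 8 and 9, numbered next to BL, and 5.30 to 5.81 in LP libraries 16 to 19.

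HADHA averaged 425 ± 45.4 CPM (SD, n = 7) in BL and 227 ± 42.4 CPM (n = 6) in STD, and PSAT1 11.2 ± 13.0 and 165 ± 87.2 CPM. HADHA lies on chromosome 3, 112753343 to 112797627, and PSAT1 on chromosome 1, 231142673 to 231172364, in Sscrofa11.1. The pyruvate dehydrogenase kinase PDK4, which spares glucose, fell (-5.80 ± 1.49, adjusted p = 0.00981), as did 3 of 8 measured genes of the mitochondrial genome, such as ND3 (-0.58 ± 0.17). Mitochondrial genes took 4.54 ± 0.624% of counts (SD) in BL and 3.23 ± 0.497% in STD. Glycolysis and glycogen genes rose in 6 of 28 cases, such as the glycogen synthase GYS1 (0.63 ± 0.13). Glucocorticoid response genes fell in 9 of 19 cases, such as TXNIP (-2.12 ± 0.46).

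In all 905 of 13517 genes passed (edgeR), 354 higher and 551 lower. As sets, fatty acid use gave camera adjusted p = 1.91e-28, and adjusted p = 0.000389 with an estimated correlation, and the amino acid response gave camera adjusted p = 1.45e-22, and adjusted p = 0.0438 with an estimated correlation. Cholesterol synthesis gave camera adjusted p = 1.3e-11, and adjusted p = 0.14 with an estimated correlation. Glycolysis gave adjusted p = 1.28e-08, and adjusted p = 0.208 with an estimated correlation. The mitochondrial genome gave adjusted p = 1.82e-06, and adjusted p = 0.302 with an estimated correlation. The glucocorticoid response gave adjusted p = 5.26e-05, and adjusted p = 0.302 with an estimated correlation. Adjusted over the list alone, 20 fatty acid genes were lower, and 26 amino acid response and 18 cholesterol genes were higher.

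BL replicate 4 stood apart from its group. Without it 654 genes passed, 464 of them shared, and the falls of the ubiquitin ligase genes FBXO32 (-4.08 ± 0.75) and TRIM63 (-1.57 ± 0.36) and of the transcription factor FOXO1 (-1.12 ± 0.26) were no longer called, at -0.68, -0.50 and -0.29. The estimate for the AMP deaminase AMPD3 turned from -3.39 ± 0.86 to 0.69. With only the STD and BL libraries in the fit 106 genes passed, 104 of them shared, and 267 without BL replicate 4. In the former PHGDH, ASNS, LSS, DHCR7, FASN, SCD, GYS1 and ND3 were no longer called, with adjusted p from 0.0571 to 0.246. Without BL replicate 4 PDK4 moved from -5.80 ± 1.49 to -4.75 (adjusted p = 0.0334). HADHA (-0.91), CPT2 (-1.54), PSAT1 (3.66) and ASNS (2.60) passed without that library. The median of the glucocorticoid response list (limma voom) was -0.59 with it and -0.23 without it. With all BL libraries fast fibre (0.26) and lymphocyte (0.51) genes lay higher, and fibroadipogenic (-0.23) genes lay lower (median log2 difference, camera adjusted p 6.82e-05 to 0.0416, and 0.498 to 0.755 with an estimated correlation). The score difference of fast fibre genes moved from 0.33 to 0.12 without BL replicate 4, and that of fibroadipogenic genes moved from -0.17 to -0.25 without BL replicate 4. Without BL replicate 4 macrophage markers (limma voom median 0.67 against 0.42 with it, camera adjusted p = 0.0159) lay higher, and extracellular matrix genes (-0.14 against 0.08 with it, camera adjusted p = 0.0169) lay lower. Without STD replicate 4 the lymphocyte list (limma voom median 0.48 against 0.56 with it, camera adjusted p = 0.247) no longer passed, and slow fibre genes (-0.39 against -0.12 with it, camera adjusted p = 0.0333) lay lower.

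**Figure D2:**
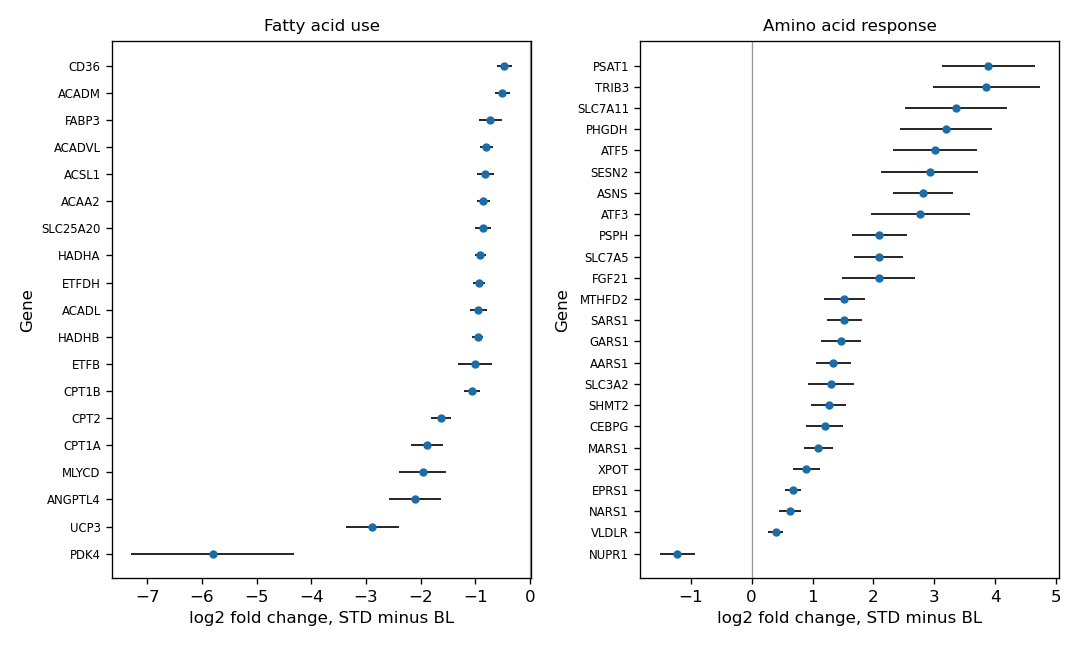
Log2 difference between STD and BL with its SE (horizontal axis) for called members of the fatty acid use and amino acid response lists (vertical axis). Fatty acid use genes lie below 0, and amino acid response genes lie above 0 except NUPR1.

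The comparison of LP-STD with STD-STD asks how muscle of pigs that began on the low protein diet differed from that of pigs kept on the standard diet, both being on the standard diet in the second period. In LP-STD amino acid response genes lay higher with a median log2 difference of 0.45 (camera adjusted p = 2.81e-11, and adjusted p = 0.461 with an estimated correlation). Their score lay higher in 3 of 3 sets of runs (exact permutation p = 0.30 over the 6 means of runs). Across sets, run 2 of LP-STD (4.81) lay below runs 1 (4.84) and 3 (4.89) of STD-STD. Markers of slow fibres lay lower with a median of -0.39 (camera adjusted p = 5.26e-05, and adjusted p = 0.482 with an estimated correlation), 7 of 13 when adjusted over the list alone, and the score lay lower in 3 of 3 sets of runs (exact permutation p = 0.30 over the 6 means of runs). Macrophage markers lay lower with a median of -0.57 (camera adjusted p = 8.56e-06, and adjusted p = 0.482 with an estimated correlation), and the score lay lower in 3 of 3 sets of runs (exact permutation p = 0.20 over the 6 means of runs). PDK4 had the lowest p among the higher genes (4.87 ± 1.02, adjusted p = 0.124, n = 12 per group), and the gluconeogenesis gene PCK1 lay at -2.32 ± 0.60, adjusted p = 0.215.

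Of 13032 genes 0 passed the edgeR test, with 1319 at an unadjusted p under 0.05, 0 by limma voom with quality weights and 8 by DESeq2. PDK4 averaged 488, 9.74 and 19.3 CPM in the 3 runs of LP-STD (n = 4 each) and 8.97, 3.97 and 4.54 CPM in those of STD-STD. With counts summed over runs 0 genes passed. In LP-STD fast fibre (0.11) genes lay higher, and extracellular matrix (-0.12) and lymphocyte (-0.35) genes lay lower (median log2 difference, camera adjusted p 0.000137 to 0.00436, and 0.482 to 0.577 with an estimated correlation). Over the means of runs the scores of these lists gave exact permutation p of 0.20 to 0.50, and of them fast fibre scores went that way in all 3 sets. The score difference of lymphocyte genes moved from -0.15 to -0.10 without STD-STD replicate 6.

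The comparison of LP-STD10 with LP-STD asks how muscle differed with 10% more lysine after restriction. Amino acid response genes fell in 15 of 35 cases and rose in 0. The genes of serine synthesis fell, PHGDH (-2.55 ± 0.53, adjusted p = 0.0117), PSAT1 (-2.52 ± 0.46, adjusted p = 0.00597) and PSPH (-1.26 ± 0.24), as did ASNS (-1.44 ± 0.28, adjusted p = 0.00724), the amino acid transporter SLC7A5 (-1.24 ± 0.23, adjusted p = 0.00597), the transcription factor ATF5 (-2.35 ± 0.46) and the hormone FGF21 (-1.87 ± 0.41). Arginase ARG2 (-1.84 ± 0.34), the mitochondrial PCK2 (-2.24 ± 0.53) and the insulin signalling kinase AKT2 (-0.41 ± 0.07, adjusted p = 0.00494) also fell. The arrestin-domain gene ARRDC2 rose (1.06 ± 0.24, adjusted p = 0.0282). Its means in the 3 runs were 29.0, 31.3 and 11.5 CPM in LP-STD10 and 14.8, 9.03 and 10.6 CPM in LP-STD (n = 4 each). It was among the genes that differed between runs of one group. AASS, which begins lysine breakdown, was at 0.28 ± 0.13, adjusted p = 0.322.

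PSAT1 averaged 117 ± 93.3 CPM (SD, n = 12) in LP-STD and 20.4 ± 8.83 CPM (n = 12) in LP-STD10, and ASNS 228 ± 95.8 and 83.4 ± 34.1 CPM. ASNS lies on chromosome 9, 77318341 to 77336290, and SLC7A5 on chromosome 6, 1545940 to 1574298, in Sscrofa11.1. The list mean was 5.20 ± 0.50 log2 CPM (SD) in LP-STD and 4.54 ± 0.19 in LP-STD10 (permutation p = 0.00014, 0.00546 adjusted over 39 lists). It lay lower in LP-STD10 in each of the 3 sets of runs, with differences of -0.86, -0.37 and -0.76 (exact permutation p over the 6 means of runs 0.10, the smallest it can give). The score of the genes that break down branched-chain and other amino acids was 4.80 ± 0.05 in LP-STD10 and 4.93 ± 0.11 in LP-STD (permutation test, adjusted p = 0.0172, and exact p = 0.10 over the means of runs). Respiratory chain genes lay lower with a median of -0.13 (camera adjusted p = 5.05e-15, and adjusted p = 0.403 with an estimated correlation), and their score lay lower in 2 of 3 sets of runs (exact permutation p = 0.20 over the 6 means of runs). Macrophage markers lay higher with a median of 0.70 (camera adjusted p = 2.88e-06, and adjusted p = 0.403 with an estimated correlation), 11 of 13 when adjusted over the list alone, and the score lay higher in 2 of 3 sets of runs (exact permutation p = 0.20 over the 6 means of runs). LP-STD10 replicate 10 had a macrophage score of 5.19 (others of its group 2.55 to 4.50), and the median (limma voom) was 0.60 with it and 0.41 without it. In LP-STD10 extracellular matrix (0.17) and lymphocyte (0.34) genes lay higher, and fast fibre (-0.06), endothelial (-0.13) and adipocyte (-0.22) genes lay lower (median log2 difference, camera adjusted p 8.04e-05 to 0.0453, and 0.403 to 0.632 with an estimated correlation). Over the means of runs the scores of these lists gave exact permutation p of 0.30 to 0.50, and of them adipocyte scores went that way in all 3 sets. Without replicate 10 the fast fibre (adjusted p = 0.656) and adipocyte lists (adjusted p = 0.0693) no longer passed camera. The score difference of fast fibre genes moved from -0.10 to -0.03 without LP-STD10 replicate 10.

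In all 53 of 13032 genes passed (edgeR), 8 higher and 45 lower. The amino acid response list gave camera adjusted p = 1.81e-19, and adjusted p = 0.124 with an estimated correlation, and 22 members were lower when adjusted over the list alone. With counts summed over runs of 4 libraries 1 gene passed, with ASNS at -1.43 (adjusted p = 0.227) and SLC7A5 at -1.28 (adjusted p = 0.0596). The count was 2 with correlated runs, 0 with 2 surrogate variables and 11 with all 67 libraries in the fit. Without LP-STD10 replicate 10, which correlated least with its group (median r = 0.942 across genes), 40 genes passed and NOTCH2 (0.43 ± 0.11), LGALS1 (0.43 ± 0.11), PLXNB2 (0.30 ± 0.07), GPT2 (-2.08 ± 0.51) and EIF4EBP1 (-0.60 ± 0.14) were no longer called, with adjusted p from 0.0595 to 0.154.

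**Figure D3:**
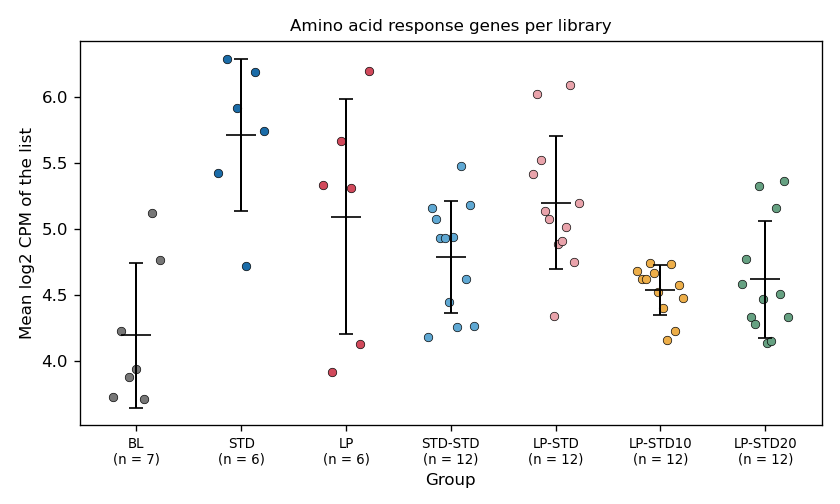
Mean log2 CPM of the amino acid response genes in each library (points) by group, with the group mean and SD as bars. STD has the highest mean and BL the lowest, and the 12 LP-STD10 libraries lie between 4.17 and 4.74.

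In the comparison of LP-STD20 with LP-STD, on 20% more lysine, PREB, a regulator of the export of secretory proteins, fell (-0.38 ± 0.07, adjusted p = 0.0118), as did the RNA helicase DDX10 (-0.47 ± 0.10, adjusted p = 0.0413) and the dihydropteridine reductase QDPR (-0.64 ± 0.14, adjusted p = 0.0413). The Hippo pathway gene MOB1B rose (0.28 ± 0.06, adjusted p = 0.0413). The amino acid response genes lay lower with a median of -0.45 (camera adjusted p = 7.86e-15, and adjusted p = 0.361 with an estimated correlation), and their score lay lower in 3 of 3 sets of runs (exact permutation p = 0.20 over the 6 means of runs). Of its 35 members 0 passed over all genes and 19 were lower when adjusted over the list alone, with ASNS at -1.05 ± 0.28, adjusted p = 0.099.

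Macrophage markers lay higher with a median of 0.88 (camera adjusted p = 3.36e-08, and adjusted p = 0.363 with an estimated correlation), 13 of 13 when adjusted over the list alone, and the score lay higher in 2 of 3 sets of runs (exact permutation p = 0.20 over the 6 means of runs). In LP-STD20 extracellular matrix (0.20) and lymphocyte (0.25) genes lay higher, and fast fibre (-0.11), endothelial (-0.10) and adipocyte (-0.42) genes lay lower (median log2 difference, camera adjusted p 9.11e-08 to 0.0107, and 0.363 to 0.543 with an estimated correlation). Over the means of runs the scores of these lists gave exact permutation p of 0.10 to 0.40, and of them extracellular matrix and endothelial scores went that way in all 3 sets. Immediate early genes lay lower with a median of -0.41 (camera adjusted p = 5.96e-05, and adjusted p = 0.444 with an estimated correlation). The score lay lower in 2 of 3 sets of runs (exact permutation p = 0.30 over the 6 means of runs), and 7 of 26 members differed between runs of one group. In all 6 of 13032 genes passed (edgeR), 2 higher and 4 lower, and these include LOC102165734 (-0.96 ± 0.16) and the glutamate transporter SLC17A7 (4.46 ± 0.90), both chosen after their values were seen. The linear trend over 0, 10 and 20% extra lysine, a contrast of the group means, is by construction the same test, with the same 6 genes, with PREB at -0.19 ± 0.04 per step of 10%. Totals were 0 with counts summed over runs, 0 with 2 surrogate variables, 107 with DESeq2 and 380 with limma voom and quality weights. The latter gave 44 for LP-STD10 against LP-STD, and at an unadjusted p under 0.05 edgeR had 2078 genes for LP-STD20 and 1872 for LP-STD10. The difference between both lysine levels was not tested. LP-STD20 replicate 9 correlated least with its group (median r = 0.955 across genes, others 0.967 or more), and the gene tests were not repeated without it.

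Across the 4 second-period groups 66 of 13032 genes differed in the joint edgeR test. They included PDK4 (adjusted p = 0.00516), the transcription factor KLF11 (adjusted p = 0.0010), UCP3 (adjusted p = 0.0357), PSAT1 (adjusted p = 0.00516), SLC7A5 (adjusted p = 0.00516) and AKT2 (adjusted p = 0.000592). AKT2 averaged 172 ± 19.2 CPM (SD, n = 12) in STD-STD, 168 ± 17.6 in LP-STD, 126 ± 19.6 in LP-STD10 and 137 ± 14.2 in LP-STD20. SLC7A5 averaged 68.2 ± 35.9, 102 ± 32.8, 43.1 ± 10.1 and 50.7 ± 21.5 CPM in the same order. With counts summed over runs of 4 libraries 0 genes passed, and with correlated runs 2.

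Against pigs that were never restricted, LP-STD10 had higher PDK4 (5.84 ± 1.06, adjusted p = 0.0033), KLF11 (2.34 ± 0.36, adjusted p = 0.000673), UCP3 (1.47 ± 0.30, adjusted p = 0.0102), ARRDC2 (1.26 ± 0.24) and CPT1A, which admits fatty acids to mitochondria (0.99 ± 0.21). Genes that fell were PSAT1 (-1.91 ± 0.45, adjusted p = 0.0346), AKT2 (-0.44 ± 0.07, adjusted p = 0.000673), the glycogen-targeting phosphatase subunit PPP1R3B (-0.97 ± 0.21) and the sterol regulator INSIG1 (-0.92 ± 0.23). Fatty acid synthesis genes lay lower with a median of -0.47 (camera adjusted p = 9.73e-06, and adjusted p = 0.823 with an estimated correlation), and the score lay lower in 3 of 3 sets of runs (exact permutation p = 0.10 over the 6 means of runs). Cholesterol synthesis genes lay lower with a median of -0.20 (camera adjusted p = 7.85e-05, and adjusted p = 0.823 with an estimated correlation), and the score lay lower in 2 of 3 sets of runs (exact permutation p = 0.20 over the 6 means of runs). Adjusted over the list alone, 7 of 21 fatty acid synthesis genes were lower and 1 was higher. In the same comparison slow fibre (-0.40) and endothelial (-0.10) genes lay lower (median log2 difference, camera adjusted p 7.85e-05 to 0.00669, and 0.823 with an estimated correlation). Over the means of runs the scores of these lists gave exact permutation p of 0.30 to 0.40, and of them slow fibre scores went that way in all 3 sets. The score difference of endothelial genes moved from -0.11 to -0.07 without LP-STD10 replicate 3. Without LP-STD10 replicate 10 the endothelial list no longer passed (adjusted p = 0.0885), and fast fibre genes lay higher (limma voom median 0.13, camera adjusted p = 0.000978).

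In all 52 of 13032 genes passed (edgeR), 14 higher and 38 lower. The fatty acid use score was 5.63 ± 0.23 in LP-STD10 and 5.33 ± 0.16 in STD-STD (SD, n = 12 each, permutation test, adjusted p = 0.0335), and the list gave camera adjusted p = 0.229, and adjusted p = 0.874 with an estimated correlation. Without PDK4 the difference in this score moved from 0.30 to 0.14 (permutation test, adjusted p = 0.189), and over the 6 means of runs the score with PDK4 gave an exact permutation p of 0.20. It lay higher in 2 of 3 sets of runs. In 3 of 3 sets muscle proteolysis and growth signalling scores (p = 0.10 each by that test) and glucocorticoid response scores (p = 0.20) lay higher. Scores of amino acid breakdown (p = 0.10) and the amino acid response (p = 0.20) lay lower in 3 of 3 sets. PDK4 averaged 625, 371 and 9.46 CPM in the 3 runs of LP-STD10 (n = 4 each), KLF11 13.8, 12.5 and 2.49 CPM and ARRDC2 29.0, 31.3 and 11.5 CPM. The third run thus lay near the STD-STD runs in these genes. PDK4 lies on chromosome 9, 75246956 to 75260134, in Sscrofa11.1. With counts summed over runs 0 genes passed, with correlated runs 14, with all 67 libraries 17, and without LP-STD10 replicate 10 PSAT1 had an adjusted p of 0.0508.

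**Figure D4:**
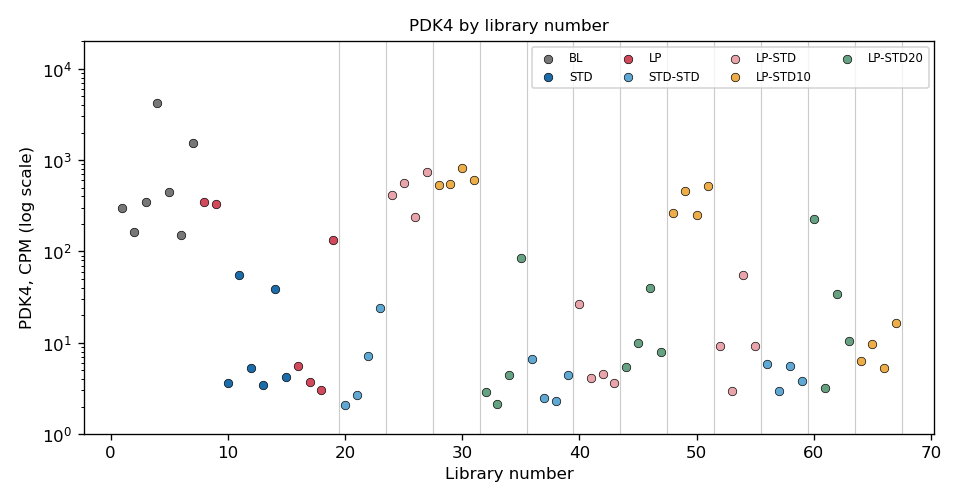
PDK4 in CPM (log scale) against library number, one point per library, coloured by group, with grey lines between runs of 4 consecutive libraries of one group in the second period. PDK4 is high in 1 run of LP-STD and 2 runs of LP-STD10 and low in the other runs of these groups.

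For LP-STD20 against STD-STD 0 of 13032 genes passed the edgeR test, with 1165 at an unadjusted p under 0.05, 0 by limma voom with quality weights and 19 by DESeq2, and 0 with counts summed over runs. The lowest p-values that did not pass belonged to the retinaldehyde dehydrogenase ALDH1A1 (-0.59 ± 0.13, adjusted p = 0.136), SH3BP5L (-0.27 ± 0.06) and AKT2 (-0.32 ± 0.07, adjusted p = 0.136) on the lower side. On the higher side they belonged to the sorting nexin SNX4 (0.36 ± 0.08, adjusted p = 0.136), IST1 (0.19 ± 0.04) and the helicase DHX9 (0.31 ± 0.07). Immediate early genes lay lower with a median of -0.56 (camera adjusted p = 8.06e-05, and adjusted p = 0.877 with an estimated correlation), 11 of 26 when adjusted over the list alone. The score lay lower in 2 of 3 sets of runs (exact permutation p = 0.40 over the 6 means of runs), 7 of 26 members differed between runs of one group, and the score difference moved from -0.45 to -0.28 without STD-STD replicate 4. PDK4 was at 2.61 ± 0.93, adjusted p = 0.379. Against STD-STD extracellular matrix (0.11) genes lay higher, and slow fibre (-0.25) and endothelial (-0.07) genes lay lower (median log2 difference, camera adjusted p 0.00686 to 0.0471, and 0.877 with an estimated correlation). Over the means of runs the scores of these lists gave exact permutation p of 0.30 to 0.40, and of them slow fibre and endothelial scores went that way in all 3 sets. The score difference of slow fibre genes moved from -0.17 to -0.11 without STD-STD replicate 1 and -0.10 without STD-STD replicate 5.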

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

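The interaction of single genes and the Y-linked covariate were tested as planned, and the list test of the interaction, correlated runs and the tests weighing explanations for the ribosomal protein genes were chosen only after the result was seen. Libraries far from the others of their group were sought in 66 sets of values of groups with 4 to 10 libraries, and chance flags about 1 in 20 groups. Of the 11 found, 8 belong to BL replicate 4. Its list scores were 6.92 (others 5.55 to 5.92) for muscle proteolysis, 10.84 (others 12.01 to 12.47) for fast fibres and 5.67 (others 6.82 to 7.63) for the extracellular matrix. They were 8.13 (others 8.81 to 9.15) for glycolysis, 2.35 (others 2.90 to 3.28) for cholesterol synthesis and 0.14 (others 1.60 to 2.41) for cell division. FBXO32, a ubiquitin ligase gene of muscle wasting, stood at 1501 (others 12.3 to 39.3) CPM and PDK4 at 4196 (others 152 to 1553) CPM in this library.

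In LP replicate 2 the immediate early score was 3.23 (others 2.30 to 2.60) and FOS was at 43.3 (others 1.09 to 13.0) CPM. In STD replicate 4 the cell division score was 1.82 (others 2.46 to 2.78).

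The change between periods differed between pigs that began on the low protein and on the standard diet in 22 genes, by the test of the interaction itself (edgeR). With correlated runs of 4 libraries 0 genes passed (limma voom), with 857 at an unadjusted p under 0.05. Ribosomal protein genes had a median interaction of 0.33 (limma voom).

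Ribosomal protein genes lay lower in LP than in STD, and these 12 libraries are also part of the interaction. The scaling of libraries was argued against by the gap of -0.26 on the log2 scale between their median and that of all other genes tested, since one factor per library moves all genes alike. Camera compares a list with the other genes, so this gap was already part of the result and is no separate evidence. A general shift of short abundant transcripts was argued against by respiratory chain genes, whose median was -0.00063 against an upper quartile of -0.21 for ribosomal protein genes. A steady drift with library number was argued against by LP libraries 8 and 9, numbered before the STD libraries. Their mean score lay -0.23 from that of STD, and both (7.49 and 7.61) lay below all 6 STD libraries. The separation of LP from STD was known before this check was chosen. STD libraries were numbered 10 to 15 in an unbroken block, so a state shared by that block cannot be told apart from the diet. An effect of the restricted diet may remain, as a hypothesis, but litter and reads shared with pseudogenes were not tested, with the Y-linked covariate the median (limma voom) was -0.25, and with an estimated correlation the list gave adjusted p = 0.249.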

How the results depend on the processing

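Sums over runs, correlated runs, the numeric slope and the fits without single libraries were tests chosen only after the results were seen. Counts of genes past the threshold were 0 for LP against STD, 0 for LP-STD against STD-STD, 53 for LP-STD10 against LP-STD, 6 for LP-STD20 against LP-STD, 6 for the lysine trend, 66 for the joint test, 52 for LP-STD10 against STD-STD, 0 for LP-STD20 against STD-STD, 2150 for STD-STD against STD, 22 for the interaction and 905 for STD against BL. Counts that moved by over 1.5 times follow. With DESeq2 counts were 129 for LP against STD, 8 for LP-STD against STD-STD, 171 for LP-STD10 against LP-STD, 107 for LP-STD20 against LP-STD, 107 for the lysine trend, 218 for the joint test, 147 for LP-STD10 against STD-STD, 19 for LP-STD20 against STD-STD and 83 for the interaction. With limma voom with quality weights counts were 380 for LP-STD20 against LP-STD, 380 for the lysine trend, 129 for the joint test and 73 for the interaction. With 2 surrogate variables counts were 1 for LP against STD, 0 for LP-STD10 against LP-STD, 0 for LP-STD20 against LP-STD, 0 for the lysine trend and 128 for LP-STD10 against STD-STD. With all 67 libraries in the fit counts were 1 for LP against STD, 1 for LP-STD against STD-STD, 11 for LP-STD10 against LP-STD, 35 for the joint test and 17 for LP-STD10 against STD-STD. With only the groups compared in the fit counts were 52 for the interaction and 106 for STD against BL. With only the groups compared and no BL replicate 4 it was 267 for STD against BL. With blocks of 16 consecutive library numbers counts were 10 for LP-STD20 against LP-STD and 10 for the lysine trend. With no count filter it was 124 for the joint test. With lysine as a numeric slope it was 2 for the lysine trend. With counts summed over runs of 4 libraries counts were 1 for LP-STD10 against LP-STD, 0 for LP-STD20 against LP-STD, 0 for the lysine trend, 0 for the joint test and 0 for LP-STD10 against STD-STD. With correlated runs of 4 libraries counts were 2 for LP-STD10 against LP-STD, 1 for LP-STD20 against LP-STD, 1 for the lysine trend, 2 for the joint test, 14 for LP-STD10 against STD-STD and 0 for the interaction. With a threshold of 0.10 counts were 2 for LP against STD, 164 for LP-STD10 against LP-STD, 64 for LP-STD20 against LP-STD, 64 for the lysine trend, 187 for the joint test, 130 for LP-STD10 against STD-STD and 42 for the interaction. The causes were not tested.

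Lists past the threshold with the preset correlation numbered 9 for LP against STD, 18 for LP-STD against STD-STD, 21 for LP-STD10 against LP-STD, 21 for LP-STD20 against LP-STD, 21 for the lysine trend, 12 for LP-STD10 against STD-STD, 10 for LP-STD20 against STD-STD, 13 for STD-STD against STD, 15 for the interaction and 15 for STD against BL. With an estimated correlation they numbered 1 for the interaction and 2 for STD against BL and 0 for the others. Over the comparisons planned for list tests they numbered 118 and, with an estimated correlation, 2. Without STD replicate 4 they numbered 15 for LP against STD. On sums over runs with an estimated correlation 0 lists passed in the second-period comparisons. Not all lists past the threshold with the preset correlation are described above.

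Of 3703 values of 303 named gene results under alternatives 3110 kept their direction and side of the threshold, 557 lost the call, 32 gained it and 4 turned direction, while 3 more had no adjusted p from DESeq2. These 4 are AMPD3 in STD against BL, at 0.31 with 2 surrogate variables, 0.21 with limma voom with quality weights, 0.69 without BL replicate 4 and 0.69 with only the groups compared and no BL replicate 4, against -3.56 without STD replicate 4. No group had 2 to 5 libraries, so the gene tests were not repeated without each library in turn. Low depth limits CDHR5 and SLC17A7, with average log2 CPM of -2.09 and -1.48.

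Same replicate numbers were not treated as pairs, though weak correlations cannot exclude a pairing such as shared litters, which are not given per library. Correlations of same-numbered deviations ranged from -0.31 to 0.31, and libraries correlated best with their own number in 0 of 6 in LP against STD, 2 of 12 in LP-STD against STD-STD, 2 of 12 in LP-STD10 against LP-STD, 2 of 12 in LP-STD20 against LP-STD, 1 of 12 in LP-STD10 against STD-STD, 3 of 12 in LP-STD20 against STD-STD, 1 of 6 in STD-STD against STD and 1 of 6 in STD against BL. In LP-STD against STD-STD 6 of 12 same-numbered pairs lay over 0.1, with a median of 0.08 against -0.005 for other pairs. In the remaining comparisons the medians of same-numbered pairs ranged from -0.08 to 0.06. With the replicate number as a block counts were 0 for LP against STD, 0 for LP-STD against STD-STD, 61 for LP-STD10 against LP-STD, 29 for LP-STD20 against LP-STD, 29 for the lysine trend, 84 for the joint test, 54 for LP-STD10 against STD-STD, 0 for LP-STD20 against STD-STD, 1924 for STD-STD against STD, 7 for the interaction and 724 for STD against BL.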

Other observations

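The counts over other splits of the libraries were planned, and the tests by runs of 4 libraries and of the fibre share were chosen only after the results were seen. Between STD and STD-STD, 3 of 13 myogenesis genes rose and 1 fell (camera adjusted p = 0.157, and adjusted p = 0.806 with an estimated correlation). As single genes the acetylcholine receptor subunits CHRNA1 (1.39 ± 0.47) and CHRND (1.71 ± 0.52), the transcription factor MYOG (0.48 ± 0.15), the atrial myosin light chain MYL4 (4.46 ± 1.25) and cardiac troponin TNNT2 (3.07 ± 0.81) rose (log2 ± SE, edgeR, n = 6 and 12). The imprinted gene DLK1 fell (-0.93 ± 0.28). The glucocorticoid-induced FKBP5 fell (-1.59 ± 0.40). MYL4 and CHRND had adjusted p of 0.171 and 0.051 with limma voom and quality weights, and CHRNA1 of 0.0522 with 2 surrogate variables and 0.0642 without STD replicate 4. With correlated runs (limma voom) the adjusted p were 0.206 for MYL4, 0.111 for CHRND and 0.117 for CHRNA1.

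The score of amino acid transport genes was 3.64 ± 0.11 (SD, n = 6) in STD and 3.26 ± 0.20 (n = 7) in BL (exact permutation test, adjusted p = 0.0195). In LP-STD the score of erythroid markers was -0.37 ± 0.35 against 0.12 ± 0.26 in STD-STD (SD, n = 12 each, permutation test, adjusted p = 0.0343, and exact p = 0.10 over the 6 means of runs). Both scores are low on the log2 CPM scale. The list had too few measured members in the second-period fit for the camera test.

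Other splits of the same libraries were counted by genes past the threshold, or, for LP against STD, LP-STD against STD-STD and LP-STD20 against STD-STD, at an unadjusted p under 0.05. The splits with as many genes, the real one included, were 4 of 100 for LP against STD (real 1139, highest other 1684), 1 of 100 for LP-STD10 against LP-STD (real 53, highest other 12) and 2 of 100 for LP-STD20 against LP-STD (real 6, highest other 18). They were 1 of 100 for the lysine trend (real 6, highest other 1), 2 of 100 for the joint test (real 66, highest other 265) and 1 of 100 for LP-STD10 against STD-STD (real 52, highest other 3). They were 1 of 60 for STD-STD against STD (real 2150, highest other 223), 1 of 60 for the interaction (real 22, highest other 2) and 1 of 60 for STD against BL (real 905, highest other 496). The lysine trend is the same test as LP-STD20 against LP-STD, with libraries of 3 groups shuffled, so its share is no separate evidence. For LP against STD 4 of 100 is too near 5 of 100 to exclude chance assignment of single libraries, and 0 genes passed there. In the other comparisons above it can be excluded only as far as libraries are independent. The runs of 4 put this in doubt for second-period libraries, and BL and STD libraries were also numbered in unbroken blocks. Chance assignment can also not be excluded where the splits with as many genes were 5 of 100 for LP-STD against STD-STD (real 1319, highest other 1853). The same holds for LP-STD20 against STD-STD with 8 of 100 (real 1165, highest other 2040). For LP-STD20 against LP-STD and the joint test a split with several times the real count points to a structure among the libraries. At the threshold the 3 comparisons counted by unadjusted p had 0 genes in the real split. Other splits of them called up to 42 for LP against STD, 7 for LP-STD against STD-STD and 29 for LP-STD20 against STD-STD.

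Some splits along the runs of 4 libraries gave as many genes as the real split or more. Of the 10 ways to split 6 whole runs, those with at least the real count for LP-STD10 against LP-STD (real 53) gave 58 (LP-STD runs 1 and 2 with LP-STD10 run 1), 504 (LP-STD run 1 with LP-STD10 runs 1 and 2) and 1019 (LP-STD runs 1 and 3 with LP-STD10 run 2), each against the other runs. For LP-STD20 against LP-STD (real 6) they gave 68 (LP-STD runs 1 and 2 with LP-STD20 run 3) and 953 (LP-STD runs 1 and 3 with LP-STD20 run 2), and for LP-STD10 against STD-STD (real 52) 177 (STD-STD runs 1 and 2 with LP-STD10 run 3). For LP-STD against STD-STD (real 0) the highest other count was 512. With counts summed over runs the real splits gave 1, 0, 0 and 0 genes in the same order, and so few splits allow no share under 0.05.

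PDK4 differed between runs of one group, as did 4 of 28 fatty acid use genes in all (CPT1A, CPT1B, PPARD and PDK4). Libraries of a run may share a state besides their diet. In the test of runs within all 4 second-period groups together 740 genes differed, and at most 2 after shuffling libraries among runs. Circadian (3.48e-08), heat shock (3.4e-06), glucocorticoid response (4.09e-06), immediate early (0.00447) and myogenesis genes (0.0371) were enriched among them (Fisher's exact test, adjusted p), and the labels give neither the time of day nor the order of sampling, which were not tested. The myogenesis genes that differed between runs were MUSK, MYF6, MYOD1 and MYOG. An effect of 10% more lysine alike in every run cannot be told apart from this: fatty acid use scores without PDK4 in LP-STD10 lay 0.25, 0.21 and -0.05 from those of STD-STD in the 3 sets of runs (permutation p of their spread 0.0628).

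The genes of the amino acid response fell as a list score in LP-STD10 against LP-STD. A lower share of fibre RNA was argued against by fast fibre genes, whose median log2 difference was -0.0552 against an upper quartile of -0.18 for amino acid response genes. Differences between runs cannot be told apart from the diet, since the exact permutation p over the 6 run means was 0.1, the smallest it can give, although all 3 sets of runs went the same way and 3 of 35 members differed between runs. An effect of lysine supply on these genes stays open as a hypothesis.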
